A study of Arabidopsis thaliana with 9 samples.

How the data were processed

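RNA was extracted from whole seedlings with a column kit, labelled with biotin and hybridised to 1-colour arrays, per the labels' protocols. Seedlings were grown for 17 days at 21 degrees Celsius in long days on plates. Each of the 3 lines (wild type, hog1-7, ddm1-12) had 3 arrays, which the labels call biological replicates. The arrays were mapped to lines by their titles, and all 9 value columns matched a sample.

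The deposited values are log2 expression values made by the authors with robust multi-array average (RMA), per the submitters' processing notes, which give no version. RMA corrects background, forces a common distribution on the probes and summarises the probes of a probe set. It compresses differences among dim probe sets, so a fold change from a wild type level near background depends on that background. The distribution of the deposited values was close but not identical between arrays, with medians from 5.11 to 5.24 and maxima from 13.4 to 13.5. No raw array files were used here. No scan dates, slides or other batch labels were used here either, so a batch that coincides with a line cannot be told apart from the line.

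From these values, 64 control probe sets were left out and 22746 probe sets were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) over all 9 arrays, so that the 3 lines shared an estimate of the spread. There was no filter on dim probe sets. The comparisons were hog1-7 against wild type, ddm1-12 against wild type and hog1-7 against ddm1-12. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

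Probe sets were named through the platform annotation and updated through gene identifiers to symbols and locus names of the TAIR10.1 assembly's RefSeq table. Of the tested probe sets, 13513 had 1 gene, 13436 of which matched a locus of that table, 503 had several and 8730 had none here. No probe set with several genes was named. No genome build is given for the probe sets in the sources used here, so no coordinates are printed. The table was used for names, for its gene classes and for which genes neighbour each other. HOG1, SAHH2 and DDM1 had no named probe set, so the planned check of the mutated genes was not made.

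Gene lists were fixed before the data were examined, 19 from loci and 6 from rules on names. Only 44 of the 376 genes in the 19 lists were named here. A list was tested when at least 5 genes were measured, which left 6 lists, while 12 lists had 1 to 4 genes and 7 had none. Each was tested with limma's camera with a preset correlation of 0.01, with 1 probe set per gene, the brightest over the 9 arrays, and Benjamini-Hochberg adjustment over the lists of a comparison. The planned list of transposable elements needed gene descriptions that the tables used here do not carry. The RefSeq pseudogene class of 923 probe sets was used in its place, which was chosen after the data and the annotation had been seen, and its camera p-values are unadjusted. Chloroplast-encoded genes were taken by their chromosome in that table. The rule for methyltransferases also named descriptions, so the 8 genes of that list are only those with the word in a symbol or synonym.

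Named genes followed a rule fixed before the data were examined. For each mutant against wild type they were the 10 largest rises and 10 largest falls among probe sets with 1 gene that passed the threshold and whose 3 mutant arrays all lay on the same side of the 3 wild type arrays. For hog1-7 against ddm1-12 the rule took 5 each way. Up to 4 passing members were named of each list that passed and 1 of each list that did not, with the 10 largest changes shared by the mutants and 5 opposite ones. HOG1, SAHH2 and DDM1 were to be named in every comparison.

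Overlap of calls was tested with one-sided Fisher's exact tests. Because both mutants share the wild type arrays, 100 draws of unchanged arrays with the fitted spread gave the overlap, correlation and covariance without an effect. The procedures were tested on simulated data with 200 changed probe sets among 22746. For hog1-7 against wild type, 77.6% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2 were recovered. For ddm1-12 against wild type the shares were 77.6%, 98.5% and 100%, and for hog1-7 against ddm1-12 they were 85.1%, 100% and 100%. Unchanged probe sets made up 5.64%, 3.16% and 6.40% of the calls in these comparisons, so the share of false calls was above 5% in 2 of the 3.

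Alternatives were fits of only the lines compared, the replicate number as a block, median centring, quantile normalization, a filter on a mean log2 of at least 5, a trended and robust variance model, array weights, a minimum log2 fold change of 1, an adjusted p under 0.01, each array left out in turn, an estimated correlation in camera and the mean over a gene's probe sets. Leaving out probe sets ending _s_at and _x_at was added after the data had been seen.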

Results

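Transcript levels were measured on 9 single-colour oligonucleotide arrays, each hybridised with RNA from whole Arabidopsis thaliana seedlings 17 days old. The seedlings belonged to 3 lines with 3 arrays each. The lines were the wild type line C2S1 and a pair of mutants from a study of transcriptional silencing associated with polyploidy. The mutant hog1-7 is named for HOG1, the S-adenosylhomocysteine hydrolase of the methyl cycle, and ddm1-12 for DDM1, a chromatin remodeller needed for DNA methylation of heterochromatin. The design asks which endogenous transcripts differ between each mutant and the wild type, and whether the mutants differ from each other. Each array gave log2 values for 22746 tested probe sets and 64 control probe sets. Array medians lay between 5.11 and 5.24 on the log2 scale. Replicates of a line correlated with Pearson r between 0.994 and 0.997 across probe sets, arrays of hog1-7 and ddm1-12 with r between 0.989 and 0.991, and wild type arrays with mutant arrays with r between 0.969 and 0.982. No array duplicated another. The number of arrays per line limits the precision of every value below.

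The annotation used here named 1 gene for 13513 of the tested probe sets, several genes for 503 and none for 8730. HOG1, its paralogue SAHH2 and DDM1 were not among the named genes, so the transcript of each mutated gene could not be used to check the line labels and is not analysed here.

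In hog1-7, the largest rises belonged to loci that RefSeq classes as pseudogenes, a class that in Arabidopsis holds many transposable element genes. AT2G12980 rose from 2.38 ± 0.05 in wild type to 11.14 ± 0.14 in hog1-7 (log2, SD, n = 3), a log2 difference of 8.75 ± 0.08 (SE) with an adjusted p of 9.02e-13 by limma with Benjamini-Hochberg adjustment. Its wild type level was that of array background, since the 27 probe sets for bacterial transcripts lay between 2.32 and 3.61 on the wild type arrays, so the difference is a lower bound. AT2G12300 was higher by at least 8.18 on the log2 scale (adjusted p = 9.73e-11), and AT2G10640, AT1G33130, AT2G12240, AT3G30396, AT2G13160, AT2G04770, AT3G31955 and AT3G47320 completed the 10 largest rises, down to at least 7.03 for AT3G47320. Of these 10, only AT3G30396 and AT2G13160 had a wild type level above those of the bacterial probe sets, so the values of the others are lower bounds and the order among the 10 is uncertain. Of 923 pseudogene probe sets, 133 were higher in hog1-7 and 3 were lower. Among 12443 protein-coding probe sets, 1149 were higher and 1213 lower. The pseudogene class as a whole shifted upward by a mean log2 change of 0.37 (limma camera p = 2.44e-06, and p = 0.0137 with an estimated correlation), while its median change was 0.04. In this comparison, 78 of the 923 pseudogene probe sets carry the ending _x_at and 111 the ending _s_at, which mark probes shared by several similar transcripts, so the copy that was transcribed is uncertain for those. All of the 10 loci named above except AT3G47320 were read by such probe sets, so their rises may not come from separate loci. With such probe sets left out, 56 of 734 pseudogene probe sets were higher and 2 lower. The mean log2 change of the class was then 0.16. The 7.63% higher among these lay under the 9.23% of protein-coding probe sets, and over the 30 of 734 that was the highest count in 100 draws of protein-coding probe sets ending _at with like wild type levels.

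QQS, an orphan gene whose silencing depends on DNA methylation, was among the genes fixed in advance as depending on that mark. It rose from 7.04 ± 0.13 to 10.21 ± 0.09 (log2, SD, n = 3), an 8.96-fold difference (log2 fold change 3.16 ± 0.08 SE, limma adjusted p = 1.71e-09). AT4G08680, a Mutator-like element on the same list, stood at 2.65 ± 0.09 in wild type and 2.81 ± 0.28 in hog1-7 (adjusted p = 0.656), and MPC had a log2 difference of 0.06. The probe set of AT4G08680 ends in _s_at, so the copy it reads is uncertain.

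Among named genes, the largest falls in hog1-7 were in protein-coding genes. OCT1 (AT1G73220), an organic cation transporter of the carnitine transporter family, fell from 8.61 ± 0.24 to 3.77 ± 0.23 (log2, SD, n = 3), which was 28.6-fold lower (log2 fold change -4.84 ± 0.15 SE, limma adjusted p = 4.31e-09). AT5G20790 was 9.25-fold lower, AT1G08310 was 9.21-fold lower and AT2G20670 was 9.19-fold lower. HIS1-3, a linker histone induced by drought, was 5.91-fold lower (adjusted p = 0.000148). The remaining named falls, AT1G64590, AT5G17340, AT3G07350, AT1G09500 and AT1G19200, lay between log2 changes of -2.91 and -2.50, where the value of AT5G17340 is a bound because its level in hog1-7 was within those of the bacterial probe sets.

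Among the gene lists fixed in advance, 6 had at least 5 named genes and were tested. Cell cycle and DNA replication was tested on 5 of its 32 fixed genes. Cold, drought and abscisic acid response was tested on 5 of 19. Flavonoid and anthocyanin synthesis was tested on 5 of 17, and photosynthesis on 6 of 40. Cell cycle and DNA replication genes were shifted upward in hog1-7 (mean log2 change 0.53, camera adjusted p = 0.00307), a call that was lost with an estimated correlation (adjusted p = 0.266). Of the 5 named here, the Aurora kinases AUR1, AUR2 and AUR3 rose, by log2 changes of 0.83, 0.79 and 0.49, and 2 did not pass the threshold. The list alone, adjusted over the list alone, also gave 3 higher. Cold, drought and abscisic acid response genes were shifted downward (mean log2 change -0.89, camera adjusted p = 0.00197, and adjusted p = 0.266 with an estimated correlation), and 4 of 5 fell, or 5 adjusted over the list alone. COR15A, a chloroplast protein of cold acclimation, was 3.52-fold lower (adjusted p = 0.0219), with values of 8.58 ± 0.26 in wild type and 6.76 ± 1.10 in hog1-7 (log2, SD, n = 3). Its call was lost with a trended, robust variance model (adjusted p = 0.0845), without wild type replicate 1 (adjusted p = 0.0809) and without wild type replicate 3 (adjusted p = 0.0552). The dehydrins LTI30 and COR47 were 1.99-fold and 1.40-fold lower, with LTI30 not passing without wild type replicate 1 (adjusted p = 0.0541), and COR15B fell by 0.46 on the log2 scale at levels within those of the bacterial probe sets. Chloroplast-encoded genes were slightly lower as a group (69 genes, mean log2 change -0.15, camera adjusted p = 0.00197, and adjusted p = 0.568 with an estimated correlation). Of them, ndhJ and ndhK, subunits of the chloroplast NADH dehydrogenase-like complex, and the photosystem genes psbC and psbN fell, and the list counted 1 lower when adjusted over the list alone. Without hog1-7 replicate 3 the list no longer passed (mean log2 change -0.07, adjusted p = 0.0629), and without hog1-7 replicate 1 its mean was -0.25.

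The other tested lists did not pass in hog1-7. Flavonoid and anthocyanin synthesis had an adjusted p of 0.0735, with the reductase DFR 1.65-fold higher (adjusted p = 0.0049), and it passed at an adjusted p of 0.0497 when only the wild type and hog1-7 arrays were fitted, at 0.0469 without wild type replicate 3 and at 0.0328 without hog1-7 replicate 2. Photosynthesis had an adjusted p of 0.163, with 1 of 6 genes lower, PSAN at a log2 change of -0.28, and 2 lower adjusted over the list alone. Methyltransferases had an adjusted p of 0.846, with 3 of 8 higher and 1 lower, and 3 higher and 2 lower adjusted over the list alone. That list holds only genes with the word methyltransferase in a symbol or synonym. From lists too small to test, the methionine methyltransferase MMT was 0.22 higher on the log2 scale, the cytokinin response regulator ARR15 was 0.54 higher, the root hair expansin EXPA7 was 0.35 higher, and the clock gene GI had a log2 change of -0.37. The Rubisco methyltransferase homologue LSMT-L had a log2 change of -0.50. The calls of MMT, PSAN, AUR3, COR15B, ARR15, GI, EXPA7, psbN, ndhK and psbC in hog1-7 were each lost without at least 1 of the arrays, and their direction was kept. Those of MMT, AUR3, GI, EXPA7, ndhK and psbC were also lost with another scaling of the arrays or a fit of only the arrays compared.

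Over all tested probe sets, 2319 were higher and 2321 lower in hog1-7 than in wild type (limma, adjusted p under 0.05), which is 20.4% of them, and 577 of these differed by at least 1 on the log2 scale. The 3' minus 5' difference of the GAPDH control, a measure of RNA integrity, was 0.67 ± 0.08 in hog1-7 and 0.65 ± 0.16 in wild type (log2, SD, n = 3, two-sided exact permutation p = 1, where 3 against 3 arrays cannot go below 0.1). That of the actin control was larger, at 3.98 ± 0.22 in hog1-7 and 3.94 ± 0.06 in wild type (exact permutation p = 0.9). The size of the 3' excess thus depended on the control.

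In ddm1-12, pseudogene loci again held all 10 of the largest named rises. Of these, only AT3G47320 and AT4G05640 were read by probe sets ending _at. AT2G12300 rose from 3.19 ± 0.31 in wild type to 11.78 ± 0.08 (log2, SD, n = 3), a log2 difference of 8.59 (± 0.16 SE, limma adjusted p = 5.43e-11). AT2G10640 and AT2G12980 were higher by log2 differences of 8.38 and 8.27, and the wild type levels of all 3 were within those of the bacterial probe sets, so these are lower bounds. AT4G05640, the only one of the 10 that was not also among the 10 largest rises of hog1-7, rose by at least 7.40 on the log2 scale in ddm1-12 and at least 6.20 in hog1-7, from a wild type level of 3.29, also within those of the bacterial probe sets. In all, 242 of 923 pseudogene probe sets were higher and 3 lower, against 940 higher and 1563 lower of 12443 protein-coding probe sets. The class shifted by a mean log2 change of 0.64 (camera p = 3.31e-19, and p = 0.000605 with an estimated correlation), with a median of 0.10. With probe sets ending _s_at or _x_at left out, 126 of 734 were higher and 3 lower. The mean was then 0.31. QQS was 8.57-fold higher (adjusted p = 1.35e-09), and AT4G08680 rose from 2.65 ± 0.09 to 6.48 ± 0.43, at least 14.2-fold (adjusted p = 2.83e-07). MPC had a log2 difference of -0.17.

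**Figure D1:**
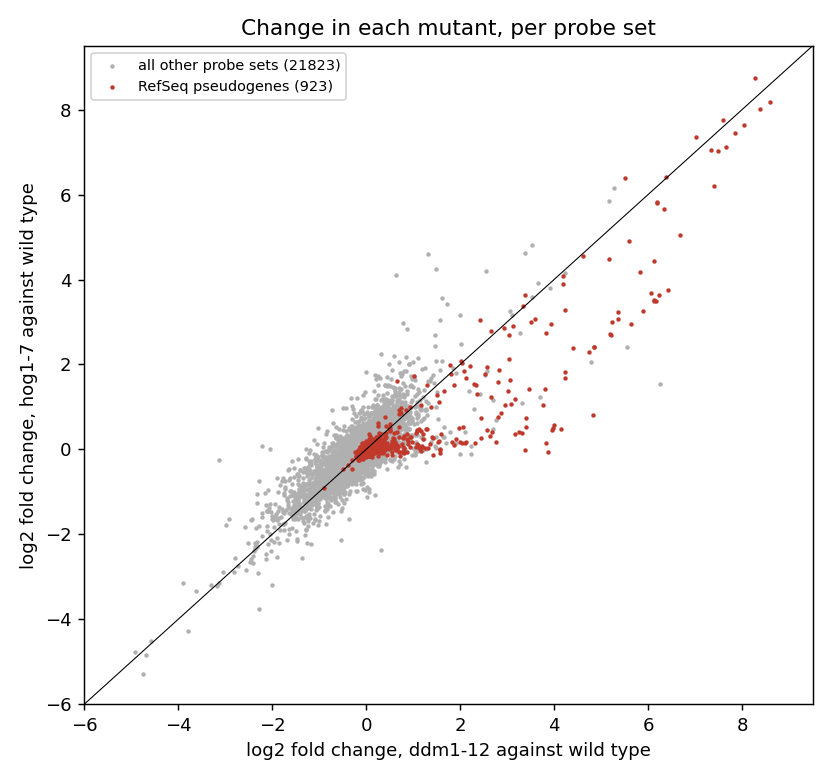
Log2 fold change of each of 22746 probe sets in ddm1-12 (horizontal) and hog1-7 (vertical) against wild type, with 923 RefSeq pseudogene probe sets in red, all others in grey and the line of equal change in black. The pseudogenes with the largest rises lie near the line, and others rise in ddm1-12 with little change in hog1-7.

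Among named genes, OCT1 had the largest fall in ddm1-12 as in hog1-7. It was 25.6-fold lower (adjusted p = 3.84e-09), AT1G08310 was 9.89-fold lower and AT5G20790 was 9.01-fold lower. AT4G22490 fell from 8.49 ± 0.16 to 5.35 ± 0.28 (log2, SD, n = 3), which was 8.82-fold lower (adjusted p = 3.34e-06). HIS1-3 was 6.92-fold lower, COR15A was 5.99-fold lower, and ChiC, a class V chitinase, was 5.48-fold lower. AT5G17340, again down to the level of the bacterial probe sets, AT1G19200 and AT5G45310 made up the rest of the 10.

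Of the fixed lists, 2 passed in ddm1-12. Cell cycle and DNA replication genes were shifted upward (mean log2 change 0.62, camera adjusted p = 0.00224, and adjusted p = 0.374 with an estimated correlation). AUR1 and AUR2 rose by log2 changes of 0.73 and 0.94, and PRL, a subunit of the replicative helicase, by 0.58, so that 3 of 5 were higher, or 5 adjusted over the list alone. Cold, drought and abscisic acid response genes were shifted downward (mean log2 change -1.04, camera adjusted p = 0.00459, and adjusted p = 0.471 with an estimated correlation), with COR15A, LTI30, COR47 and COR15B lower, 4 of 5, and 5 adjusted over the list alone. Chloroplast-encoded genes had a mean log2 change of 0.06 (adjusted p = 0.176), with 2 of 69 higher, or 0 adjusted over the list alone, among them rpl20 at 0.46. Its mean was 0.02 without ddm1-12 replicate 3 and 0.12 without ddm1-12 replicate 2, and the list passed in the latter case (adjusted p = 0.0251) and with array weights (adjusted p = 0.0459). Photosynthesis (adjusted p = 0.176, PSAN at a log2 change of -0.33), flavonoid and anthocyanin synthesis (adjusted p = 0.501) and methyltransferases (adjusted p = 0.68, LSMT-L at a log2 change of -0.27) did not pass. ARR15 was 1.77-fold higher. The calls of COR47, COR15B, LSMT-L and rpl20 in ddm1-12 were each lost without at least 1 of the arrays, and their direction was kept. Those of COR15B and LSMT-L were also lost with median centring.

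In total 2105 probe sets were higher and 2929 lower in ddm1-12, 22.1% of those tested, and 656 of these differed by at least 1 on the log2 scale. The split of calls depended on scaling: with each array's median subtracted, 2818 were higher and 2480 lower. It also depended on ddm1-12 replicate 2, which had the lowest array median, 5.11. Without that array 2142 were higher and 2405 lower. Without ddm1-12 replicate 1 the counts were 1581 and 2561, and without replicate 3 they were 1568 and 2477. The GAPDH 3' minus 5' difference was 0.73 ± 0.15 in ddm1-12 (log2, SD, n = 3, two-sided exact permutation p = 0.5 against wild type). The actin difference was 3.90 ± 0.12 in ddm1-12 (exact permutation p = 0.6 against wild type).

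**Figure D2:**
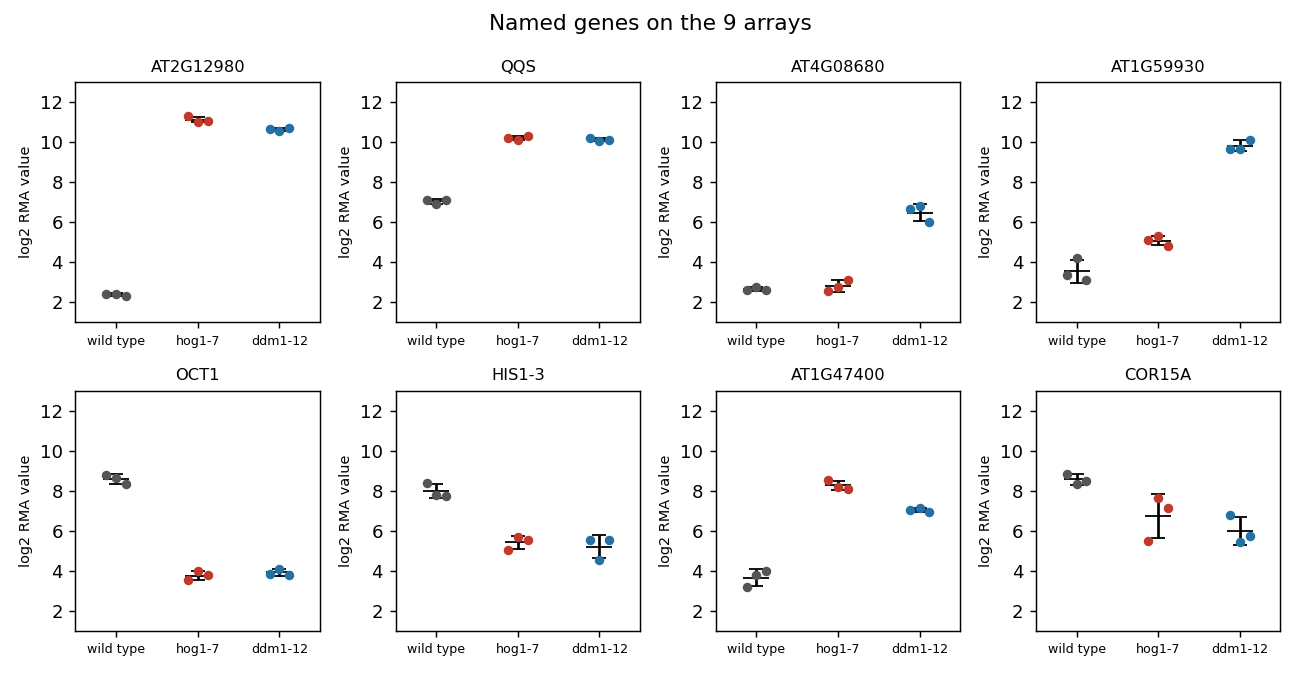
Log2 RMA value of 8 genes on each of the 9 arrays (points) with the mean and SD of each line (bars, n = 3). AT2G12980 and QQS were higher in both mutants, AT4G08680 and AT1G59930 mainly in ddm1-12, OCT1, HIS1-3 and COR15A were lower in both mutants, and AT1G47400, chosen after its values were seen, was higher in both.

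The genes that changed in the mutants overlapped. Of the probe sets called in each mutant, 1313 were higher in both and 1721 lower in both, where independent lists would share 215 and 299. By one-sided Fisher's exact test the log10 p was -904 for the shared rises and -1227 for the shared falls. That test treats probe sets as independent, which they are not, and both lists use the same wild type arrays. Its p-values therefore overstate the evidence. The 10 genes with the largest change in both were pseudogenes, led by AT2G12980, AT2G12300 and AT2G10640. All of them but AT3G47320 were read by probe sets ending _s_at or _x_at. Of the pseudogene probe sets called higher in hog1-7, 97.0% were also called higher in ddm1-12. Of the 242 called higher in ddm1-12, 129 were also called higher in hog1-7 and 113 were not, and 71 of the 113 differed between the mutants by the direct test. Protein-coding probe sets numbered 620 higher in both and 897 lower in both, with 840 called in hog1-7 only and 981 in ddm1-12 only. The log2 fold changes of the mutants correlated with Pearson r = 0.843 across probe sets, which are not independent replicates, and their covariance was 0.181. Unchanged groups simulated against shared control arrays gave a mean covariance of 0.0059, a mean r of 0.501 and at most 1 probe set called the same way in both. The changes had the same sign in 76.5% of probe sets, against a mean of 66.7% in the simulated groups. The 3 wild type arrays could not be split into parts of 2 or more, so some of the excess in shared calls over independent lists may come from the shared controls.

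Calls in opposite directions were rare, at 11 probe sets higher in hog1-7 and lower in ddm1-12 and 5 the other way. The named ones with the largest changes were AT1G48670, CCS, AT5G12880, AT5G44400 and GSTU27. CCS, the copper chaperone of superoxide dismutase, stood at 7.92 ± 0.28 in wild type, 7.50 ± 0.17 in hog1-7 and 8.60 ± 0.06 in ddm1-12 (log2, SD, n = 3). GSTU27, a glutathione transferase, stood at 7.67 ± 0.10, 7.94 ± 0.06 and 7.10 ± 0.10 in the same order. For each of these 5 genes the call against wild type was lost in at least 1 of the mutants without at least 1 of the arrays, and for AT1G48670, CCS, AT5G44400 and GSTU27 also with another scaling of the arrays.

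Compared directly, hog1-7 had lower pseudogene transcript levels than ddm1-12. Of 923 pseudogene probe sets, 140 were lower in hog1-7 and 5 higher, and the class differed by a mean log2 change of -0.28 (camera p = 8.81e-18, and p = 0.000757 with an estimated correlation). With probe sets ending _s_at or _x_at left out, 67 of 734 were lower and 2 higher. The mean was then -0.15. Among the 129 pseudogene probe sets called higher in both mutants, the median rise was 1.72 in hog1-7 and 3.08 in ddm1-12 on the log2 scale, and 69 were lower in hog1-7 by the direct test. AT1G59930, a protein-coding locus read by an _x_at probe set, was 26.6-fold lower in hog1-7 (5.08 ± 0.25 against 9.82 ± 0.27, log2, SD, n = 3, limma adjusted p = 1.45e-06). The pseudogenes AT1G12720, AT2G05470, AT4G08680 and AT1G36590 were lower by log2 differences of -4.02, -3.92, -3.67 and -3.66, and in hog1-7 AT2G05470 and AT4G08680 lay within the levels of the bacterial probe sets, so that these values are bounds on the size of the difference. All of these pseudogenes but AT1G12720 were read by probe sets ending _s_at.

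Protein-coding genes led the values that were higher in hog1-7 than in ddm1-12. AT5G24240 was the most different (7.49 ± 0.16 against 4.03 ± 0.25, log2, SD, n = 3, log2 fold change 3.46 ± 0.12 SE, limma adjusted p = 5.49e-08) and AT1G20400 was 9.74-fold higher, and both were also above wild type in each mutant. AT4G22490 was 7.44-fold higher because of its fall in ddm1-12, AT5G19890 was 4.52-fold higher, and AT4G33720 was 6.80-fold higher with a wide spread in ddm1-12 (6.26 ± 1.46, SD, n = 3). The call for AT4G33720 was lost when only the mutant arrays were fitted (adjusted p = 0.0591) and with a trended, robust variance model (adjusted p = 0.114). It was also lost without hog1-7 replicate 1 (0.0943) or 2 (0.0933) and without ddm1-12 replicate 1 (0.0954) or 3 (0.116).

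Among the fixed lists, flavonoid and anthocyanin synthesis genes were higher in hog1-7 than in ddm1-12 (mean log2 difference 0.38, camera adjusted p = 0.00212, and adjusted p = 0.0813 with an estimated correlation). DFR was 1.72-fold higher, and 1 of 5 genes passed over all probe sets, or 4 adjusted over the list alone. Without ddm1-12 replicate 3 the adjusted p of DFR was 0.0531. Chloroplast-encoded genes were lower (mean log2 difference -0.22, camera adjusted p = 1.66e-11, and adjusted p = 0.554 with an estimated correlation, mean -0.14 without hog1-7 replicate 3), with ndhJ at a log2 difference of -0.49 as the only 1 of 69 that passed, also when adjusted over the list alone. The call of ndhJ was lost without hog1-7 replicate 2 (adjusted p = 0.0576) and without ddm1-12 replicate 3 (adjusted p = 0.0627). Photosynthesis (adjusted p = 0.957), methyltransferases (adjusted p = 0.957), cell cycle and DNA replication (adjusted p = 0.667), and cold, drought and abscisic acid response (adjusted p = 0.989) did not pass, and the mean of the last list was 0.15 where its median was -0.01. The root hair expansins EXPA7 and EXPA18 were 1.33-fold and 1.47-fold higher in hog1-7, and EXPA18 did not pass with median centring (adjusted p = 0.0579), quantile normalization (adjusted p = 0.0605) or a fit of only the mutant arrays (adjusted p = 0.0686). It also did not pass without hog1-7 replicate 2 (adjusted p = 0.104) or 3 (0.0706) or without ddm1-12 replicate 1 (0.0670) or 3 (0.113).

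In all, 1042 probe sets differed between hog1-7 and ddm1-12, 4.58% of those tested, and 650 of them were higher in hog1-7. The direction of this split changed with each array's median subtracted, where 434 were higher and 560 lower. After quantile normalization the split was nearly even, at 493 higher and 471 lower. The count of 1042 fell to 554 without hog1-7 replicate 2, to 685 without ddm1-12 replicate 1 and to 553 without ddm1-12 replicate 3.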

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

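The pseudogene class was chosen after the data had been seen, as were the tests of the shared wild type arrays, of growth and harvest, of probe sets shared between copies and of matched draws among probe sets ending _at. The other matched draws and the slopes used that class, and were set before their own results were seen, as were the splits of the arrays.

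The mutants differed from each other by a direct test in several results, which is why these are given here. Of all probe sets, 1042 differed between hog1-7 and ddm1-12. The fixed lists of flavonoid and anthocyanin synthesis and of chloroplast-encoded genes differed by mean log2 values of 0.38 and -0.22 (hog1-7 minus ddm1-12), and neither list passed with an estimated correlation (adjusted p of 0.0813 and 0.554). Pseudogenes differed by a mean of -0.28. Among named genes, hog1-7 was higher for AT5G24240 (3.46), AT1G20400 (3.28), AT4G22490 (2.89), AT4G33720 (2.77), AT5G19890 (2.18), AT1G48670 (0.87), GSTU27 (0.83), DFR (0.78), ChiC (0.78), AT5G12880 (0.74), AT5G44400 (0.72), EXPA18 (0.56), AT2G12980 (0.49) and EXPA7 (0.42), all as log2 differences. It was lower for AT1G59930 (-4.74), AT1G12720 (-4.02), AT2G05470 (-3.92), AT4G08680 (-3.67), AT1G36590 (-3.66), AT4G05640 (-1.20), CCS (-1.10), AT2G04770 (-0.54), ndhJ (-0.49) and AT3G47320 (-0.45). The values of AT1G48670, AT2G05470 and AT4G08680 are bounds, since the lower of the levels compared was within those of the bacterial probe sets.

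Control probe sets, which the comparisons did not use, also differed from wild type. In hog1-7 the log2 differences were 0.26 for the middle actin probe set, 0.30 and 0.31 for the 3' and middle GAPDH probe sets, and 0.43 and 0.38 for the 3' and 5' probe sets of another GAPDH design. In ddm1-12 they were 0.23 and 0.29 for the 3' GAPDH probe sets of these designs. None of 18 spike-in probe sets passed the threshold of limma in any of the comparisons.

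Both mutants differed from wild type in many of the same genes. Of all probe sets, 3034 were called the same way in both, 1590 in hog1-7 only and 1984 in ddm1-12 only. The covariance of the mutants' log2 fold changes was 0.181. The highest of 100 simulated draws of unchanged groups sharing the wild type arrays was 0.00652. These covariances argue against noise of the shared arrays as the cause. Growth, harvest or labelling of the wild type arrays apart from the mutants cannot be told apart from an effect of the mutations, since the sources used here give no batch. The largest difference between mutant and wild type arrays in a 3' minus 5' control value was 0.0822 on the log2 scale. It was that of GAPDH in ddm1-12, where the SDs were 0.150 in ddm1-12 and 0.164 in wild type. For ubiquitin both mutants lay above wild type, hog1-7 by 0.0659 and ddm1-12 by 0.0594. The ubiquitin SDs were 0.0741, 0.0752 and 0.0438 in hog1-7, ddm1-12 and wild type. These values do not bear on growth or harvest. An effect common to both mutations stays open, untested.

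Pseudogenes were higher in both mutants. The rise was not confined to the endings _s_at and _x_at, since among probe sets ending _at 56 were higher and 2 lower in hog1-7. Probe sets with those 2 endings carried much of it: without them the class mean in hog1-7 fell from 0.37 to 0.16. The ending was the only check, so probes shared between copies are not excluded as a source of the rest. A skew of dim probe sets is argued against by protein-coding probe sets matched on the wild type mean: the highest of 100 draws had 38 higher in hog1-7, against 133 pseudogenes, and 46 in ddm1-12, against 242. Among probe sets ending _at alone the highest draw had 30 in each mutant, against 56 and 126 pseudogenes, although the 7.63% higher in hog1-7 lay under the 9.23% of all protein-coding probe sets. Loss of silencing at these loci may explain the rise, as a hypothesis, under the limit on growth and harvest given above for all differences from wild type.

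Pseudogenes were lower in hog1-7 than in ddm1-12. Among probe sets ending _at, 67 were lower and 2 higher, so the difference was not confined to the endings _s_at and _x_at. The ending was the only check, so probes shared between copies are not excluded as a source. Slopes of hog1-7 against ddm1-12 log2 fold changes were fitted over probe sets called in either mutant. The fit was orthogonal and through the origin, so it treats both mutants alike and is not an ordinary regression. They were 0.991 (SE 0.0321) over 3343 protein-coding probe sets and 0.739 (SE 0.0323) over 250 pseudogene probe sets. Of the latter, 114 were called in ddm1-12 only and 5 in hog1-7 only. The SEs are from a bootstrap over probe sets and give no spread over plants. For these called probe sets and this kind of fit, the slopes argue against a uniformly smaller effect in hog1-7. An ordinary regression slope was not fitted. The shared wild type arrays enter both fold changes, and their part in the slopes was not tested. A weaker release of these loci in hog1-7 may account for the lower pseudogene levels, as a hypothesis that was not tested on other lines or alleles.

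The splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real splits called 4487, 4499 and 718 probe sets for hog1-7 against wild type, ddm1-12 against wild type and hog1-7 against ddm1-12, in fits of the 6 arrays compared. In each, the highest of the other splits called 0, so 1 split, the real one, reached its count.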

How the results depend on the processing

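Leaving out probe sets ending _s_at and _x_at, and all values of the pseudogene class, were chosen after the data had been seen. With a log2 fold change of at least 1 required, the counts were 577 (hog1-7 against wild type), 656 (ddm1-12 against wild type), 191 (hog1-7 against ddm1-12) and 388 changed the same way in both. With an adjusted p under 0.01 they were 2533, 2823, 426 and 1640. Stricter thresholds lower counts by construction.

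The covariance of the mutants' log2 fold changes was 0.281 with a filter on a mean log2 of at least 5 and 0.126 without probe sets ending _s_at and _x_at (jackknife SE of the reported value 0.0191). The cause was not tested. Of the lists, 1, 0 and 1 passed in the 3 comparisons with the filter, which left 3 lists to test, and 0, 0 and 0 with an estimated correlation. Pseudogenes called higher in hog1-7, higher in ddm1-12 and lower in hog1-7 than in ddm1-12 numbered 63, 63 and 42 with the filter, 88, 146 and 83 with a log2 fold change of at least 1, and 56, 126 and 67 without probe sets ending _s_at and _x_at, where fewer probe sets were tested. The class means in these comparisons were 3.47, 4.62 and -1.15 with the filter, whose mean over all arrays includes the mutants' own rises, and 0.16, 0.31 and -0.15 without probe sets ending _s_at and _x_at.

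With each array left out in turn, the counts ranged from 3258 to 4839, 3555 to 4915 and 553 to 978 in the 3 comparisons, and from 2108 to 2883 for the same way in both. The covariance ranged from 0.17 to 0.192. Lists that passed ranged from 2 to 4, 2 to 3 and 2 to 2. Pseudogene means ranged from 0.35 to 0.38, 0.63 to 0.65 and -0.29 to -0.27, and their counts from 118 to 139, 211 to 240 and 123 to 144.

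Means of lists that did not pass changed sign, and the cause was not tested. Methyltransferases in hog1-7 were at -0.0030 with the filter and ranged from -0.00881 to 0.0619 with an array left out, the negative value without hog1-7 replicate 3. In hog1-7 against ddm1-12 photosynthesis was at -0.032 with median centring. With an array left out, the means in that comparison ranged from -0.0115 (without hog1-7 replicate 3) to 0.0495 for photosynthesis, from -0.203 to 0.0195 (without ddm1-12 replicate 1) for cell cycle, from -0.038 (without hog1-7 replicate 2) to 0.425 for cold response and from -0.0483 to 0.0224 for methyltransferases, which were positive without hog1-7 replicates 1 (0.00566) and 2 and without ddm1-12 replicate 3 (0.013).

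Replicate number as a block gave 4835, 5313 and 1188. The main fit did not pair the arrays by these numbers. Residuals of arrays with the same number correlated at 0.0346 to 0.169. All 9 pairs were positive, and in 7 of 9 the first array correlated best with its own number. A batch that follows the replicate number is therefore not excluded. Of 1558 values of named genes under alternatives, 1426 kept their side of the threshold, 132 no longer passed and 0 reversed, and 68 of 94 gene results were kept throughout. Values near the array background limit the folds of dim genes.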

Other observations

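The lists of iron deficiency and phosphate starvation genes, and the tests on them, were written only after the largest changes were seen, as was the grouping by symbol. The tests of neighbouring genes were set before, and the intervals of their odds ratios were added after.

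Several genes of the iron deficiency response were higher in hog1-7. AT1G47400 was 24.5-fold higher in hog1-7 and 10.5-fold higher in ddm1-12, and the transcription factor BHLH101 was at least 4.19-fold and 1.62-fold higher, from a wild type level near background. Of the 12 list members not seen before the list was written, 8 were higher and 1 lower in hog1-7, with a mean log2 change of 0.76 (camera p = 4.81e-05, and p = 0.0313 with an estimated correlation). Compared with ddm1-12 their mean was 0.51 (limma camera adjusted p = 2.71e-07), and in ddm1-12 against wild type it was 0.25 (limma camera adjusted p = 0.125), adjusted over the list with and without the members seen. These values are consistent with an iron deficiency response that was stronger in hog1-7, as a hypothesis. Iron content was not measured.

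The phosphate starvation list fixed in advance had 0 of 12 genes named here. On the later list of phosphate starvation genes, most members not seen before were lower in both mutants. Of 8 members not seen before, 6 were lower in hog1-7 and 6 in ddm1-12, with mean log2 changes of -0.46 (limma camera adjusted p = 0.000248) and -0.52 (limma camera adjusted p = 0.000706). With an estimated correlation the p-values were 0.0218 and 0.0295. A lower phosphate starvation response than in wild type may explain this, as a hypothesis, and a difference in the plates or the harvest of the wild type would give the same values. Phosphate content was not measured.

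Protein-coding genes beside a pseudogene that was higher were tested for being higher themselves. In hog1-7, 5 of 39 were, against 23 of 249 beside other pseudogenes (odds ratio 1.44, Fisher's exact p = 0.558), with a 95% interval of 0.402 to 4.24. In ddm1-12, 11 of 68 were, against 19 of 220 (odds ratio 2.04, Fisher's exact p = 0.109, interval 0.825 to 4.81). Spread to neighbours is neither shown nor excluded in either mutant.

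Of 5580 adjacent pairs of protein-coding genes, 164 were called the same way in hog1-7, against a mean of 103 and a highest of 127 in 1000 permutations, and 163 in ddm1-12, against 123 and 153. Regions with several changed genes may exist, and tandem copies with similar probes were not separated from them.

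Of 20 families grouped by symbol, 4 passed in hog1-7 against ddm1-12: EXPA (mean log2 difference 0.30, adjusted p = 0.0118), UGT (0.14, adjusted p = 0.0146), GSTU (0.26, adjusted p = 0.0205) and NET (0.15, adjusted p = 0.0446). None of these passed with an estimated correlation, with adjusted p-values of 0.231, 0.361, 0.579 and 0.656.

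Some large changes fell on probe sets with no gene named here. The largest rise among these had log2 fold changes of 5.84 in hog1-7 and 5.17 in ddm1-12, and the largest fall in hog1-7 had -5.28 and -4.74. The probe set with the largest fall in hog1-7 against ddm1-12 had the same value, 11.27, on each of the wild type arrays, and log2 fold changes of -2.37 in hog1-7 and 0.31 in ddm1-12.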
